A study of Mus musculus with 8 samples.

How the data were processed

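Gene expression was measured by RNA sequencing of 8 mouse livers, 4 from mice injected with AAV-H19 and 4 from mice injected with AAV-Null, all fed an ethanol diet. Per the labels' protocols, RNA was extracted with Direct-zol kits and poly(A) libraries were made with a strand-specific TruSeq kit. Per the submitters' processing notes, HISAT and StringTie were used; their versions and roles, the genome build, the annotation, the counting step and its strand setting are not given in the sources used here. The labels give each liver its own number and say nothing of litters, days or sequencing batches, so p-values measure the spread between these samples.

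The deposited table holds estimated counts (expected counts) per gene for 55450 Ensembl gene identifiers, not normalized by the authors as far as the values show, with a column for each sample. All values were whole numbers as deposited, so rounding changed nothing. Low values piled up at multiples of 4: per library, 820 to 990 genes had a value of 4, against 226 to 285 with 3 and 124 to 164 with 5. A unit is therefore not a read; if 4 units stand for a read pair, the libraries held 15.9 M to 20.7 M pairs. The table totals range from 63.7 M to 83.0 M units and limit the precision of each value, and counting error is larger than the units alone would give. An alternative fit with all values divided by 4 was run for this reason.

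Each column was assigned to a sample by its name, which equals the sample's description in the labels, and no column was left without a sample. All 55450 identifiers matched a symbol in GENCODE M21 (GRCm38), from which positions, biotypes and the length and GC content of the longest transcript were taken. Because the authors' build is not given in the sources used here, the positions printed are those of GRCm38 in that annotation. Library pairs were compared by Pearson's r of log2 CPM and by a chi-square statistic of values divided by 4, whose ratio to its degrees of freedom was at least 30.4, so no library was a copy of another. In all 8 libraries the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were expressed (at least 473 units) and Xist was at most 19 units.

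Genes were filtered with filterByExpr of edgeR 4.0.16 at its defaults (minimum count 10, minimum total 15), which left 16672 genes; the removed genes held 0.0454% of all counts. Libraries were scaled by TMM, and the groups were compared with edgeR's quasi-likelihood test (glmQLFit with robust estimation and glmQLFTest, no covariates) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.389. A standard error of a log2 fold change is the fold change divided by the square root of the F statistic. Before the data were examined, 35 gene lists were fixed for pathways, cell types and quality checks of ethanol-fed liver, and 34 had at least 5 tested members. These were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with an estimated correlation and with fry beside it, and members were also adjusted over the list alone. Single values per library were compared with exact two-sided permutation tests over the 70 assignments of 8 samples.

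The genes named were set by a rule fixed before the data were examined. They are H19, 7 genes of the methionine cycle and splicing (Bhmt, Mat1a, Gnmt, Ahcy, Cbs, Mat2a and Ptbp1), the 10 largest rises and 10 largest falls, and up to 4 members of each list with the smallest p among those past an adjusted p of 0.05. The largest changes had to pass an adjusted p of 0.05 with a mean of at least 1 CPM and no overlap between groups, and provisional gene names were passed over; 291 genes with such names were called. The rule gave 90 genes.

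The procedure was tested on counts simulated for this comparison with 200 changed genes. Over 16188 genes, with no length trend, 18% of the genes changed 2-fold and 90% of those changed 4-fold were recovered, and 8 unchanged genes were called. With a length trend between the groups added, over 16067 genes, 481 unchanged genes were called without the length offset and 8 with it; the offset fit recovered 8% of 2-fold and 91% of 4-fold changes. In a simulated set test, a shifted list had an adjusted p of 1.2e-13 and none of 30 unshifted lists was called. The simulated genes varied independently, so this does not show how the set test treats lists whose members move together.

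Alternatives fixed before the data were examined were DESeq2 size factors, upper-quartile factors, library sizes without H19, DESeq2 1.42.0, limma-voom, no filter and a filter of 1 CPM in 4 samples, an adjusted p threshold of 0.1, a surrogate variable from sva 3.50.0, leaving out each library in turn, and the other set tests. Added after seeing the data were an offset for each library's trend of log2 CPM with transcript length (natural spline, 5 degrees of freedom), the same with GC content, values divided by 4, overlapping genes on the same strand summed, and fits without AAV-Null 22 and 24, with and without the length offset. Splicing was not analysed, since the table holds totals per gene.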

Results

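Poly(A) RNA was sequenced from the livers of 8 mice fed an ethanol diet. Of these mice, 4 had been injected with an adeno-associated virus (AAV), a vector commonly used to express a gene in the liver, that is named for H19 (AAV-H19, samples 25 to 28), and 4 with AAV-Null (samples 21 to 24), the comparison virus, whose insert the labels do not describe. H19 is an imprinted long non-coding RNA that is abundant in fetal liver and low in adult liver. The deposited estimated counts summed to 63.7 M to 78.8 M units in the AAV-H19 libraries and to 78.3 M to 83.0 M in the AAV-Null libraries (70.5 ± 6.34 M against 79.8 ± 2.18 M, SD, n = 4 each; exact two-sided permutation p = 0.0857). Pearson's r across genes of log2 CPM, the count scaled to a common library total, was 0.961 to 0.967 between AAV-H19 libraries, 0.928 to 0.968 between AAV-Null libraries, and 0.897 to 0.951 between libraries of different groups. No pair of libraries differed by as little as sampling noise, so all 8 were counted as separate samples.

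H19 itself was present at 128 ± 21.4 CPM (SD, n = 4) in AAV-H19 livers and at 0.601 ± 0.562 CPM (n = 4) in AAV-Null livers. The gene (ENSMUSG00000000031) lies on the minus strand of chromosome 7 at 142575529 to 142578143 and is annotated as a long intergenic non-coding RNA. Its estimated counts were 7024 to 10148 in the AAV-H19 libraries and 10 to 112 in the AAV-Null libraries, so each of the 8 libraries matched its label. The log2 fold change was 7.73 ± 0.66 (SE), with an adjusted p of 0.00134 by edgeR's quasi-likelihood test. The exact two-sided permutation p was 0.0286, the smallest that 4 samples against 4 allow.

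**Figure D1:**
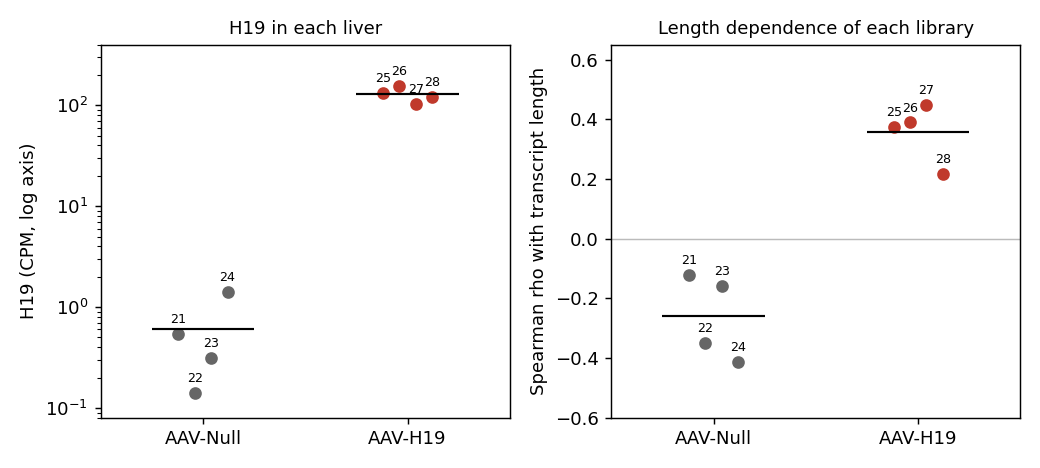
Left, H19 in CPM on a log axis in each liver; right, the Spearman rho across protein-coding genes between a library's log2 CPM, relative to the mean of all 8 libraries, and the length of the longest annotated transcript. Points are single libraries with their sample numbers and bars are group means; H19 was 104 to 155 CPM in AAV-H19 and 0.142 to 1.41 CPM in AAV-Null, and rho was 0.218 to 0.449 in AAV-H19 and -0.413 to -0.122 in AAV-Null.

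The comparison of the groups asked which transcripts differed in ethanol-fed liver when H19 was delivered. Among genes with a symbol that is not a provisional one, the largest rises besides H19 were in Adnp, Scd2, Kidins220, Fam83h, Ankfy1, Itgav, Mier1, Atp7a and Mfsd4a. Scd2, a stearoyl-CoA desaturase, rose by 4.19 ± 0.61 on the log2 scale (SE, adjusted p = 0.00823), from 0.312 ± 0.211 to 5.78 ± 2.27 CPM (SD, n = 4 each, edgeR). Kidins220, a membrane scaffold of growth factor receptor signalling, rose by 3.48 ± 0.26, from 4.64 ± 1.57 to 51.8 ± 4.50 CPM, and the integrin subunit gene Itgav rose by 3.08 ± 0.44. Atp7a, which encodes a copper-transporting ATPase, rose by 2.92 ± 0.29, and Ankfy1 and Mier1 rose by 3.10 ± 0.43 and 3.07 ± 0.38. Fam83h and Mfsd4a rose by 3.23 ± 0.72 and 2.80 ± 0.52; Fam83h was at 6.02 CPM in AAV-Null 22 and 0.478 to 1.05 CPM in the other 3 AAV-Null livers, and without AAV-Null 22 its log2 change was 4.66. These 9 genes have transcripts of 3288 to 8030 nt, and with the length offset described further on all but Fam83h passed (edgeR adjusted p = 0.0757). Adnp had the highest fitted change, 8.52 ± 0.27, but its reads lie in a span shared with a readthrough gene on the same strand. With the counts of overlapping genes summed, an alternative chosen after seeing the data, its log2 change was 0.09 ± 0.15 (edgeR adjusted p = 0.723).

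Among the largest falls, Mettl7a1, which encodes a methyltransferase-like protein, fell by 3.15 ± 0.23 on the log2 scale (SE, edgeR adjusted p = 0.000711), from 307 ± 77.3 CPM in AAV-Null to 34.5 ± 6.56 CPM in AAV-H19 (SD, n = 4 each). Usp50 had a log2 change of -3.98 ± 1.05 (edgeR adjusted p = 0.0409), but it was at 15.7 CPM in AAV-Null 24 and at 0.651 to 1.85 CPM in the other 3 AAV-Null livers. Without AAV-Null 24 its log2 change was -1.88 and with overlapping genes summed -1.23 ± 0.43, and it did not pass in either fit. The pseudogenes Rpl17-ps5, Mup-ps14, Rps12-ps24, Rpl12-ps1, Rpl27-ps3, Rps19-ps1 and Rps18-ps1 were also among them, with log2 changes of -3.28 to -2.34 and transcripts of 381 to 555 nt. With the length offset described further on, Rpl17-ps5 passed among these 7. Without AAV-Null 22 the log2 changes of Rpl17-ps5, Rps12-ps24 and Rps18-ps1 were -2.61, -1.96 and -1.64. Pseudogenes can share reads with their parent genes, so these 7 values are uncertain.

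In all, 934 genes were higher and 1012 lower in AAV-H19 livers out of 16672 tested (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05; 4968 genes at an unadjusted p under 0.05). The groups did not overlap in 3956 genes, or 23.7%, where chance gives 2.86% for 4 samples against 4. The protein-coding genes that were higher had a median transcript length of 5642 nt and those that were lower 1359 nt, against 3352.5 nt for all 13538 protein-coding genes tested. Across these genes, which are not independent replicates, Spearman's rho between log2 fold change and transcript length was 0.502, and with GC content -0.00645. Each library's own rho with length was 0.358 ± 0.0987 in AAV-H19 and -0.261 ± 0.143 in AAV-Null (SD, n = 4 each, exact two-sided permutation p = 0.0286). With each library's length trend taken out as an offset, an alternative chosen after seeing the data, 235 genes were higher and 134 lower, of which 212 and 119 were also called without it. The counts also depended on single libraries: without AAV-H19 25, 26, 27 or 28 there were 128, 206, 86 or 373 higher and 53, 98, 27 or 325 lower genes, and without AAV-Null 24 there were 679 and 498. Upper-quartile scaling moved the median log2 change of all genes from -0.02 to -0.13 and gave 656 higher and 1557 lower genes, or 29.6% higher against 48.0% with TMM.

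**Figure D2:**
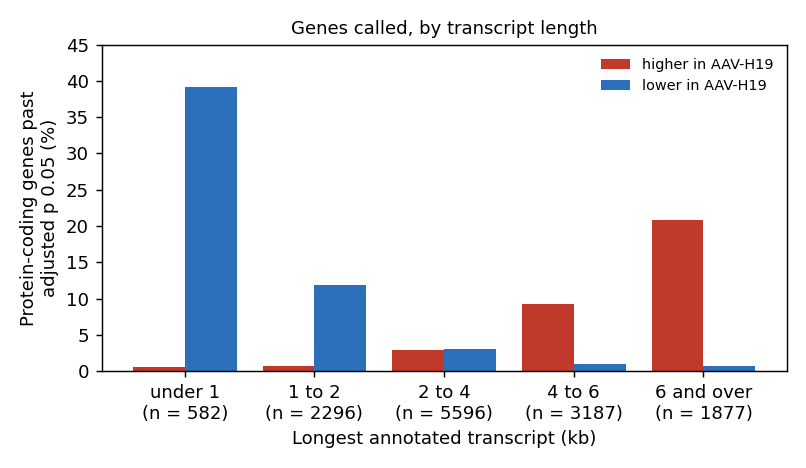
Percentage of protein-coding genes called higher (red) or lower (blue) in AAV-H19 livers (edgeR adjusted p under 0.05), by the length of the longest annotated transcript in kilobases, with the number of genes tested in each bin. Among transcripts under 1 kb, 39.2% of 582 genes were lower and 0.515% higher; among those of 6 kb and over, 20.8% of 1877 genes were higher and 0.746% lower.

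Of 84 named genes besides H19 that passed the test, 12 kept an adjusted p under 0.05 whichever library was left out and also with the length offset. They included Adnp, Scd2, Kidins220, Ankfy1, Itgav, Mier1, Atp7a, Nnat, Pdia4 and Insr, which were higher, and Mettl7a1, which was lower. These fits do not address the span that Adnp shares with a readthrough gene, and Adnp did not pass with overlapping genes summed. Nnat, an imprinted gene in an intron of Blcap, rose by 2.79 ± 0.33 on the log2 scale (SE, edgeR adjusted p = 0.00437), from 0.268 ± 0.0478 to 1.87 ± 0.493 CPM (SD, n = 4 each). With the length offset 21 of the 84 passed, and 72 of the 84 lost the call when at least 1 of the 8 libraries was left out.

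Methionine metabolism and splicing, both named in the title of the study, were examined as gene lists fixed beforehand. In methionine and one-carbon metabolism, Mat1a and Cbs rose, Pemt fell and the other 30 of 33 genes did not pass the test. Mat1a, the main methionine adenosyltransferase of adult liver, rose by 0.77 ± 0.19 on the log2 scale (SE, edgeR adjusted p = 0.036), from 5276 ± 1008 to 8973 ± 1297 CPM (SD, n = 4 each). Cbs, which condenses homocysteine with serine, rose by 0.81 ± 0.21 (edgeR adjusted p = 0.0417), and Pemt, which methylates phosphatidylethanolamine, fell by 0.83 ± 0.21 (edgeR adjusted p = 0.0387). Bhmt, which remethylates homocysteine from betaine, had a log2 change of -0.71 ± 0.43 (edgeR adjusted p = 0.299), with 2556 ± 585 CPM in AAV-H19 and 4171 ± 2969 CPM in AAV-Null. AAV-Null 22 was at 8457 CPM of Bhmt and the other 3 AAV-Null livers at 1653 to 3581 CPM, and without AAV-Null 22 the log2 change was -0.10. The log2 changes of Gnmt, Ahcy and Mat2a were -0.17 ± 0.26, 0.30 ± 0.20 and 0.45 ± 0.22, with edgeR adjusted p of 0.696, 0.337 and 0.201. Adjusted over the list alone, the counts were also 2 higher and 1 lower, and limma's camera test of the list gave an adjusted p of 0.36. Under the length offset Mat1a, Cbs and Pemt had log2 changes of 0.66, 0.38 and -0.35 and edgeR adjusted p of 0.122, 0.243 and 0.253, and their annotated transcripts are 3468, 6226 and 1003 nt long. Gnmt, whose transcript is 1035 nt long, had a log2 change of 0.31 with that offset.

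Among splicing regulators, Celf1, Mbnl2, Srsf1 and Sf3b1 rose, none of 46 fell, and 42 did not pass the test. The log2 changes were 0.89 ± 0.14 for Celf1, 1.40 ± 0.24 for Mbnl2, 0.81 ± 0.19 for Srsf1 and 0.61 ± 0.17 for Sf3b1 (SE, edgeR adjusted p = 0.0106, 0.0146, 0.0315 and 0.0478). Ptbp1, the polypyrimidine tract-binding splicing repressor, was at 60.9 ± 4.77 CPM in AAV-H19 and 55.0 ± 29.2 CPM in AAV-Null (SD, n = 4 each; log2 change 0.14 ± 0.33, edgeR adjusted p = 0.804). The list's median log2 change was 0.18, 3 members were higher adjusted over the list alone, and limma's camera test gave an adjusted p of 0.0579. The 4 genes that rose have transcripts of 5362 to 7851 nt, and with the length offset none of the 46 passed and the list's median was 0.07. Gene totals do not measure exon choice, so splicing itself was not analysed here.

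In the endoplasmic reticulum stress response, 8 of 21 genes rose, none fell, and 12 were higher adjusted over the list alone; the other 13 did not pass and 4 of them had negative fitted changes. Hyou1, an endoplasmic reticulum chaperone, rose by 2.36 ± 0.42 on the log2 scale (SE, edgeR adjusted p = 0.0154), from 30.6 ± 19.7 to 158 ± 31.6 CPM (SD, n = 4 each). The protein disulfide isomerase gene Pdia4 rose by 1.33 ± 0.20, Creld2 by 1.53 ± 0.38 and the chaperone gene Hsp90b1 by 0.91 ± 0.20 (edgeR adjusted p = 0.00931, 0.0348 and 0.0264). The list's median log2 change was 0.57 and limma's camera test with its preset correlation gave an adjusted p of 0.000602, but the adjusted p was 0.904 with an estimated correlation and 0.0892 in the fry test. The list's mean log2 CPM was 7.23 ± 0.23 in AAV-H19 and 6.54 ± 0.43 in AAV-Null (SD, n = 4 each, exact two-sided permutation p = 0.0857). Under the length offset 4 members passed and the list's median was 0.68.

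In carbohydrate and insulin signalling, Insr and Irs2 rose, and the other 17 of 19 genes of glucose metabolism did not pass. Insr, the insulin receptor, rose by 2.62 ± 0.28 on the log2 scale (SE, edgeR adjusted p = 0.00285), from 8.55 ± 3.46 to 52.5 ± 6.33 CPM (SD, n = 4 each), and Irs2, an insulin receptor substrate, rose by 1.13 ± 0.18 (edgeR adjusted p = 0.0102). Adjusted over the list alone, 3 were higher; the camera adjusted p was 0.0408 with the preset correlation, and the adjusted p was 0.904 with an estimated correlation. The list's call also ended without AAV-Null 21 (adjusted p = 0.0765), without AAV-Null 23 (adjusted p = 0.192), with a filter of 1 CPM in 4 samples (adjusted p = 0.0861), with values divided by 4 (adjusted p = 0.0598) and in the fry test (adjusted p = 0.084). The transcripts of Insr and Irs2 are 9355 and 6323 nt long, and with the length offset their log2 changes were 2.08 and 0.68 (edgeR adjusted p = 0.002 and 0.0473).

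Among genes of fatty acid and triglyceride synthesis, Scd1, Lpin2 and Acacb rose and the other 20 of 23 did not pass; 3 were higher adjusted over the list alone. Scd1, the main hepatic stearoyl-CoA desaturase, rose by 1.84 ± 0.39 on the log2 scale (SE, edgeR adjusted p = 0.0246), from 483 ± 201 to 1734 ± 924 CPM (SD, n = 4 each). Lpin2, a phosphatidate phosphatase, rose by 1.13 ± 0.21 and Acacb, an acetyl-CoA carboxylase, by 1.17 ± 0.31. In fatty acid oxidation and PPARA targets, 4 of 29 genes were higher and 1 lower over all genes tested, and likewise adjusted over the list alone. Ppara, the receptor that drives this program, rose by 1.23 ± 0.24, the acyltransferase Cpt1a by 0.75 ± 0.16 and Cyp4a32 by 0.78 ± 0.19. Among lipid droplet and uptake genes Plin5 rose by 0.79 ± 0.22 and Fitm1 fell by 0.81 ± 0.18, and 21 of 23 did not pass; 4 were higher and 4 lower adjusted over the list alone. The camera adjusted p of these 3 lists was 0.28, 0.381 and 0.876. Of the 8 genes named here only Cyp4a32 passed with the length offset, with a log2 change of 1.07 (edgeR adjusted p = 0.0228).

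Among markers of Kupffer cells and other macrophages, 8 of 19 fell, none rose, and 14 were lower adjusted over the list alone; the other 11 did not pass. The lysozyme gene Lyz2 fell by 1.49 ± 0.25 on the log2 scale (SE, edgeR adjusted p = 0.0129), from 71.3 ± 16.9 to 25.3 ± 6.52 CPM (SD, n = 4 each). The complement genes C1qa and C1qb fell by 1.08 ± 0.19 and 1.06 ± 0.24, and the Kupffer cell lectin gene Clec4f fell by 0.93 ± 0.18 (edgeR adjusted p = 0.0146, 0.0273 and 0.0213). All 19 fitted changes were negative, with a median of -0.95, and limma's camera test gave an adjusted p of 2.2e-05 with the preset correlation; the adjusted p was 0.904 with an estimated correlation and 0.084 in the fry test. The list's mean log2 CPM was 2.31 ± 0.36 in AAV-H19 and 3.16 ± 0.52 in AAV-Null (SD, n = 4 each, exact two-sided permutation p = 0.0857). With the length offset Lyz2 and Clec4f still passed, at -1.13 and -0.87, and the list's median was -0.76.

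**Figure D3:**
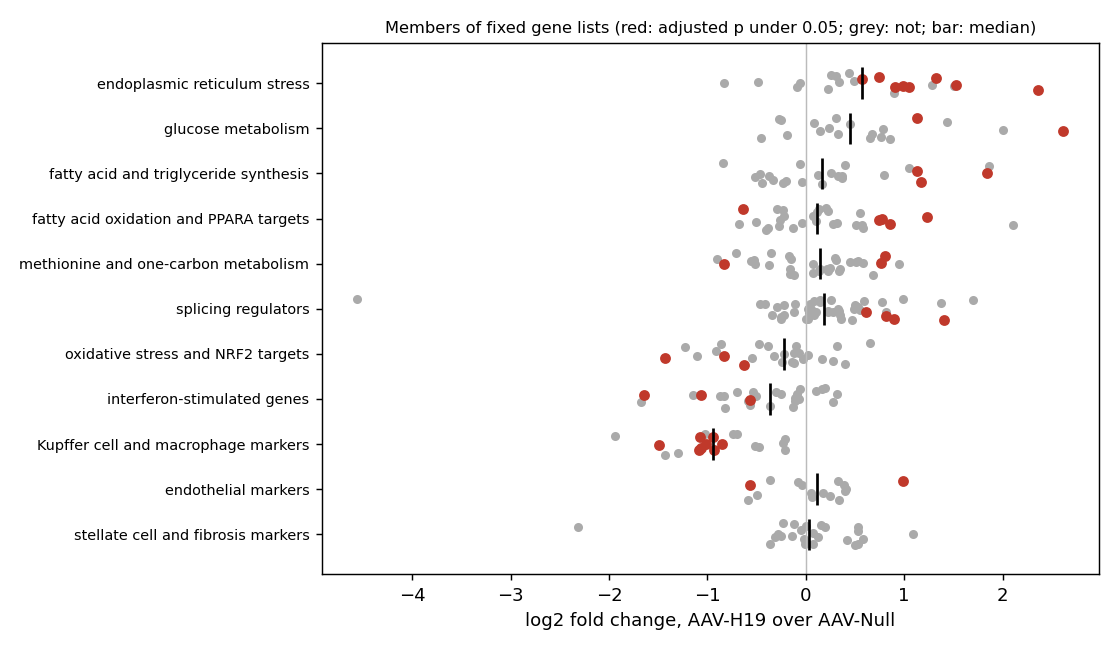
Log2 fold change (AAV-H19 over AAV-Null, n = 4 each) of the tested members of 11 gene lists; each point is a gene, red where its edgeR adjusted p is under 0.05, and the black bar is the list's median. The medians run from 0.57 for endoplasmic reticulum stress to -0.95 for Kupffer cell and macrophage markers.

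Among endothelial markers the cadherin gene Cdh5 rose by 0.99 ± 0.28 on the log2 scale and the sinusoidal lectin gene Clec4g fell by 0.57 ± 0.14, and the other 14 of 16 did not pass; 1 was higher and 1 lower adjusted over the list alone. None of 24 stellate cell and fibrosis markers passed, over all genes or adjusted over the list alone, and their median log2 change was 0.04. Of 12 cholangiocyte markers Sox9 and Pkhd1 rose by 1.27 ± 0.27 and 0.86 ± 0.24, and Krt23 fell by 2.25 ± 0.48; adjusted over the list alone, 2 were higher and 2 lower. With overlapping genes summed, Pkhd1 had a log2 change of 0.59 and did not pass. The T cell receptor gene Trbc2 fell by 1.86 ± 0.53, from 0.736 ± 0.0477 to 0.202 ± 0.114 CPM (SD, n = 4 each), and was the only one of 12 lymphocyte markers to pass, against 2 adjusted over the list alone. The lymphocyte list had a median log2 change of -0.85 with 10 of 12 members negative, and its mean log2 CPM per library differed by -0.89 with the groups fully apart (n = 4 each, exact two-sided permutation p = 0.0286, adjusted p = 0.194). Neither neutrophil nor erythroid markers held a gene that passed, among 7 and 5 tested. Of 5 tested markers of pancreas, fat and gall bladder, Plin1 and Pigr rose, by 3.80 ± 0.95 and 0.89 ± 0.23, with Plin1 at 0.0482 ± 0.0558 CPM in AAV-Null and 0.7 ± 0.0352 CPM in AAV-H19 and a log2 change of 4.40 without AAV-Null 24. The median of these 5 was 1.27, and the groups were fully apart in their mean log2 CPM (difference 1.42, exact permutation p = 0.0286, adjusted p = 0.194). The camera adjusted p of the 7 lists in this paragraph ranged from 0.0835 to 0.697, and none of the genes named in it passed with the length offset.

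Inflammatory genes gave few calls. Among 27 interferon-stimulated genes Ifi27l2a, Isg15 and Bst2 fell, by 1.65 ± 0.30, 1.06 ± 0.26 and 0.57 ± 0.16 on the log2 scale, and 3 were lower adjusted over the list alone. The transcripts of these 3 genes are 463, 756 and 792 nt long, and with the length offset their log2 changes were -0.98, -0.56 and -0.06, none past the test. Of the 27, 22 had negative fitted changes, and the list's median was -0.36 without the offset and -0.40 with it. Of 21 inflammatory mediators, Tnfaip3, an inhibitor of NF-kappa B signalling, rose by 0.91 ± 0.24, while 19 of the 21 had negative fitted changes and the list's median was -0.52. Of 25 acute-phase genes Saa3 and Apcs fell by 1.46 ± 0.42 and 1.26 ± 0.36; the median of these 25 was 0.11. Adjusted over the list alone, neither the inflammatory nor the acute-phase list held a call. Among 25 oxidative stress and NRF2 target genes the glutathione peroxidase gene Gpx4 fell by 1.43 ± 0.29, Nqo1 by 0.83 ± 0.21 and the superoxide dismutase gene Sod1 by 0.63 ± 0.16, and 4 were lower adjusted over the list alone. The camera adjusted p of these 4 lists ranged from 0.0835 to 0.628, and none of the named genes passed with the length offset.

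Hepatocyte genes moved in both directions. Of 16 hepatocyte markers the urea cycle gene Cps1 and the transcription factor gene Hnf4a rose, by 1.38 ± 0.22 and 0.85 ± 0.18 on the log2 scale, and Apoc3 and Asgr1 fell by 0.83 ± 0.20 and 0.90 ± 0.25; adjusted over the list alone, 5 were higher and 4 lower. The 2 that rose have transcripts of 5555 and 4362 nt and the 2 that fell of 709 and 1308 nt, and none passed with the length offset. Among 15 periportal genes Cps1 and Cyp2f2 rose, the latter by 1.03 ± 0.26, and among 15 pericentral genes Lect2 and Rhbg fell by 1.18 ± 0.21 and 0.95 ± 0.19. The same counts, 2 higher and 2 lower, held adjusted over each list alone, and the camera adjusted p was 0.0835 for both lists and 0.583 for hepatocyte markers. With the length offset these lists passed, at camera adjusted p of 0.0052 for periportal genes, 0.0259 for pericentral genes and 0.0183 for hepatocyte markers, with medians of 0.53, -0.50 and 0.40. Without the offset the adjusted p was 0.904 with an estimated correlation for each of the 3, and that test was not run with the offset. In 92 genes of hepatocyte-related lists the log2 change per doubling of length was 0.21 ± 0.0825 (SE). Over all protein-coding genes it was 0.369 ± 0.00612. An offset fitted over all genes may therefore shift hepatocyte genes too far, and the calls of these lists with the offset are uncertain. In the circadian clock Per1, Cry2 and Tef rose by 1.05 ± 0.24, 0.86 ± 0.21 and 0.83 ± 0.18, and Dbp, an output gene of the clock, fell by 1.47 ± 0.36; 4 of 19 were higher and 1 lower, also adjusted over the list alone. None of these 4 passed with the length offset, and the camera adjusted p was 0.11.

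Single genes passed in other lists. Hsd17b7 was the only one of 24 cholesterol synthesis genes to rise, by 1.16 ± 0.25 on the log2 scale, Abcc3 the only one of 24 bile acid genes, by 0.86 ± 0.17, and Cyp2b10 the only one of 25 xenobiotic metabolism genes, by 0.85 ± 0.24. None of 12 genes of alcohol and acetaldehyde metabolism passed in edgeR's test, over all genes or adjusted over the list alone, and their median log2 change was -0.11. Of 16 tested imprinted genes Nnat, Peg3 and Slc38a4 rose, the last pair by 0.94 ± 0.19 and 0.61 ± 0.17, and 4 were higher adjusted over the list alone. Among 9 fetal liver genes Scd2 rose and Ly6d fell by 1.49 ± 0.36, and among 19 immediate early genes Fosb rose by 1.99 ± 0.48. Of 18 genes higher in male liver Cyp4a12a rose by 1.26 ± 0.27 and Mup17 fell by 2.32 ± 0.58, and none of 14 genes higher in female liver and none of 24 cell cycle genes passed. The mitochondrially encoded mt-Nd3, 348 nt long, fell by 0.92 ± 0.18 and the other 12 of 13 such transcripts did not pass. The list itself leaned the other way, with 3 of 13 members negative and a median of 0.32, or 0.75 with the length offset. Adjusted over each list alone, none of the xenobiotic genes passed and, imprinted genes aside, the counts of these lists were unchanged. With the length offset Nnat, Scd2 and Cyp4a12a passed among the genes of this paragraph, and the camera adjusted p of these 11 lists ranged from 0.0835 to 0.87.

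Over the 34 lists tested, 3 passed limma's camera test with the preset correlation, 9 with the length offset and none with an estimated correlation. Those 9 were the same 3, the 3 hepatocyte lists above, tissue markers of pancreas, fat and gall bladder (adjusted p = 0.0259), immediate early genes (adjusted p = 0.0108) and mitochondrially encoded transcripts (adjusted p = 0.000414). For these 9, without the offset, the adjusted p was 0.898 to 0.904 with an estimated correlation. The mitochondrial list passed as higher, with a median of 0.32 without the offset and 0.75 with it. Its 13 transcripts showed no clear length trend of their own (log2 change per doubling of length 0.0233 ± 0.148, SE). An offset fitted over all genes may therefore raise them too far, and this call is uncertain. A different 3 passed the fry test of a common direction: splicing regulators (adjusted p = 0.0362), lymphocyte markers (adjusted p = 0.0497) and pancreas, adipose and gall bladder markers (adjusted p = 0.0161). When each list was reduced to its mean log2 CPM per library, the groups were fully apart for 5 lists, and the smallest exact permutation p of 0.0286 became 0.194 after Benjamini-Hochberg adjustment over the 34.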

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

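Of the tests in this part, the one on GC content and the one on the Adnp locus were chosen only after their results had been seen, as was the length offset. Among the 4 samples of a group, 1 stood apart from the other 3 by Dixon's criterion in 10 of 196 groups examined, where chance gives about 1 in 20, or 9.8. In AAV-H19 livers, Fam83h was highest in sample 27 at 23.1 CPM, Usp50 was highest in sample 26 at 0.551 CPM, Rpl12-ps1 was lowest in sample 27 at 0.089 CPM and Asgr1 was lowest in sample 27 at 371 CPM. In AAV-Null livers, Sf3b1 was lowest in sample 23 at 59.3 CPM and Hsd17b7 was highest in sample 24 at 38.0 CPM. Also in AAV-Null livers, sample 22 had the highest Cyp4a32 at 23.6 CPM and Trbc2 at 0.807 CPM, and the lowest Cdh5 at 11.4 CPM and Fosb at 0.17 CPM.

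Long transcripts were higher and short transcripts lower in AAV-H19 livers. GC content and library size argue little for themselves: rho of log2 fold change with GC was -0.00645 over 13538 protein-coding genes, and rho with length was 0.495 after all libraries were thinned to the smallest total, against 0.502 before. The slope of log2 fold change per doubling of length was 0.339 ± 0.0782 (SE) among 90 markers of non-hepatocyte cells, 0.364 ± 0.0839 without the macrophage list and 0.369 ± 0.00612 over all protein-coding genes, while it was 0.21 ± 0.0825 in 92 hepatocyte genes and 0.0233 ± 0.148 in 13 mitochondrially encoded transcripts. Length-dependent recovery or counting of RNA in whole libraries may therefore account for much of the trend, and within AAV-Null the libraries also spread along it, with rho from -0.209 in sample 22 to 0.26 in sample 21 relative to their group's mean. A change of transcript length or stability caused by H19 in all cell types was not tested and stays open, and the labels give no RNA quality or preparation day.

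Markers of Kupffer cells and macrophages were lower in AAV-H19 livers. The list's median of -0.95 lay at percentile 0 of 10000 random lists matched on length and expression. These random lists had a median of -0.21 and a middle range of -0.53 to 0.13, so length and expression alone would place the list higher. Their genes were drawn separately, so the percentile leaves out that markers of a cell type can move together. It does not measure the spread between livers, and camera with an estimated correlation gave an adjusted p of 0.904. A lower share of all non-hepatocyte cells alike would lower endothelial and stellate markers too, yet with the length offset the macrophage median lay at -0.643 relative to theirs (permutation p = 1e-05, the smallest that 100000 shuffles of list membership can give, over genes that are not independent). Lymphocyte markers were lower as well, with a median of -0.85 (-0.58 with the length offset), 10 of 12 negative and a mean per library of -0.89 in AAV-H19 relative to AAV-Null (exact permutation p = 0.0286; -0.65 with the length offset, p = 0.0571, groups overlapping), so a lower share of immune cells in general is not excluded. Whether macrophages were fewer or expressed less stays open, and so does the spread between livers, because the macrophage list's mean per library gave an exact permutation p of 0.0857 and the groups overlapped.

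Adnp was at 45.8 ± 0.396 CPM in AAV-H19 and 0.125 ± 0.0449 CPM in AAV-Null (SD, n = 4 each). Gm20716, a readthrough gene that shares its span, was looked at after these values were seen. It was at 6.13 ± 12.3 CPM in AAV-H19, with libraries from 0 to 24.5 CPM, and at 59.5 ± 12.3 CPM in AAV-Null. The log2 ratio of the summed CPM of Adnp and Gm20716, AAV-H19 over AAV-Null, was -0.20. Assignment of the same reads to either gene is therefore a candidate explanation of the change in Adnp. Dpm1, another gene summed at this locus, was at 20.4 ± 8.87 CPM in AAV-H19 and 8.24 ± 1.94 CPM in AAV-Null. With Dpm1 summed as well the log2 ratio was 0.0939. Why the assignment would differ between groups was not tested.

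Of the 35 splits of the 8 samples into 4 and 4, only 1, the real one, gave as many as 1946 genes, and the highest of the others gave 1. A rank of 1 in 35 is the best that this design allows. The other splits mix the groups, so any group difference adds to their residual spread and few calls are likely. At an unadjusted p under 0.05 (edgeR), the highest of the others had 2338 genes and the real one 4968. This count therefore does not exclude chance. With the length offset the real split gave 369 genes and the highest other 4. The size of rho between log2 fold change and transcript length was 0.502 in the real split. It was nearly as large, 0.496, in the split that put AAV-Null 21 with AAV-H19 25, 26 and 27. Chance could not be excluded for the number of gene lists either, since 29 of the 35 splits gave at least the 3 lists of the real one, and the highest other gave 18.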

How the results depend on the processing

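The length, GC, unit and overlap alternatives and those without AAV-Null 22 and 24 were chosen after seeing the data. H19 kept its direction and its call in every fit run, with log2 changes of 7.41 to 8.57 when 1 library was left out and up to 8.35 elsewhere. Leaving out 1 library gave 86 to 1023 higher genes, 27 to 1050 lower genes and 2 to 13 gene lists; the lowest counts came without AAV-H19 27 (86 and 27), then 25 (128 and 53), 26 (206 and 98) and 28 (373 and 325), and without AAV-Null 24 there were 498 lower genes. Lists numbered 13 without AAV-Null 22, 7 without 24, 9 without AAV-H19 26, and 5 without 27 or 28. Fewer samples lower the power. Leaving out an AAV-Null library moved the gene counts less than leaving out an AAV-H19 library, the list count moved most without AAV-Null 22, and the cause was not tested.

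Upper-quartile factors gave 1557 lower genes, the DESeq2 Wald test 1516 higher and 1932 lower, and a threshold of 0.1 by construction 1694 higher, 1885 lower and 10 lists. No filter gave 8 lists, a surrogate variable 10 and an estimated correlation 0. The length offset gave 235 higher, 134 lower and 9 lists, the length and GC offset 415, 318 and 9. Without AAV-Null 22 and 24 there were 13 lists, and with the length offset as well 418 lower genes and 15 lists. Except for the offsets and the threshold, the cause was not tested. Values divided by 4 (1035 and 1205 genes) and overlapping genes summed (950 and 1013) stayed within 1.5 times.

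Gnmt, not called, ranged from -0.31 without AAV-Null 23 to 0.10 without AAV-Null 22, and changed sign to 0.12 with a surrogate variable, 0.31 with the length offset, 0.23 with length and GC, 0.15 without AAV-Null 22 and 24 and 0.44 with the length offset as well. Ptbp1, not called, ranged from -0.081 without AAV-Null 24 to 0.52 without AAV-Null 23, and changed sign to -0.14 without 22 and 24 and -0.11 with the length offset as well; the cause was not tested. Of 89 named genes besides H19, no other changed sign, 63 lost the call with the length offset, and 8 to 72 lost it when 1 library was left out. No paired analysis was possible because the sample numbers 21 to 28 are each used once. At this depth and spread, 18% of simulated 2-fold changes were recovered, so a gene that did not pass is not shown to be unchanged.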

Other observations

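All groups and sums in this part were chosen after seeing the data. Short housekeeping transcripts were lower in AAV-H19 livers: 56 of 80 cytosolic ribosomal protein genes were lower and none higher (edgeR adjusted p under 0.05), with a median log2 change of -1.16, and 40 of 78 nuclear genes of the respiratory chain and ATP synthase were lower, with a median of -0.93. Their median transcript lengths were 1100 and 1025.5 nt, and with the length offset 3 and 4 genes were lower and the medians were -0.66 and -0.45. Among 38 proteasome subunits 7 were lower and none higher. Longer genes of the COPII coat and Sec61 translocon gave 6 higher and 3 lower of 24, and those of the mediator and SWI/SNF complexes 6 higher of 44. Under the length offset 1 proteasome gene was lower, 1 COPII or Sec61 gene was higher and none lower, and in the mediator and SWI/SNF group 1 was higher and 1 lower. The camera adjusted p over these 5 groups ran from 1.9e-23 to 0.154 with the preset correlation and, with an estimated correlation, the adjusted p was 0.234 to 0.271. With the length offset and the preset correlation, the camera adjusted p was 5.8e-17 for ribosomal, 2.2e-10 for respiratory chain and 0.0019 for proteasome genes. It was 0.28 for COPII and Sec61 genes and 0.702 for mediator and SWI/SNF genes. The estimated correlation was not run with the offset.

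Albumin took 8.77 ± 0.926% of all counts in AAV-H19 and 7.20 ± 0.474% in AAV-Null livers (SD, n = 4 each, exact two-sided permutation p = 0.0286), and the 10 most abundant genes 19.5 ± 0.656% and 17.8 ± 0.719% (exact permutation p = 0.0286). Mitochondrially encoded transcripts took 7.96 ± 0.319% and 7.29 ± 2.43%. Within AAV-Null they were 9.25% and 9.42% in samples 21 and 23, and 4.57% and 5.92% in samples 22 and 24.

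The fall of Mettl7a1 was not offset by its paralogs: summed with Mettl7a2 and Mettl7a3 it was at 35.3 ± 6.53 CPM in AAV-H19 and 307 ± 77.6 CPM in AAV-Null (SD, n = 4 each). Mettl7a2 alone was at 0.725 ± 0.0945 CPM in AAV-H19 and 0.433 ± 0.146 CPM in AAV-Null, and Mettl7a3 at 0.0444 ± 0.0632 and 0.136 ± 0.156 CPM. Usp50 summed with its neighbour Usp8 was at 42.4 ± 3.54 and 34.2 ± 5.38 CPM.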
